A study of Homo sapiens with 16 samples.

How the data were processed

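The data are 16 messenger RNA libraries of Jurkat and 6T-CEM cells with sh-NC or sh-SH2D1A, in 8 groups of 2. The labels describe total RNA from TRIzol, TruSeq libraries and a NovaSeq instrument, and the submitters' processing notes name HISAT2 2.2.0, StringTie and the hg38 build. As deposited by the authors, the values are counts per Ensembl gene, in 4 tables, one for each line and day. They are whole numbers and had not been normalised, and the totals differ between libraries. The annotation release, the strand setting, any filter and the step that made the counts are not given in the sources used here. If StringTie made them, they were estimated from coverage and rounded. Each table holds the same 64252 gene identifiers, of which 41784 have a symbol and 56591 are in GENCODE 29, the annotation used here for positions, strands and transcripts. Identifiers without a symbol hold between 2.44 and 3.10% of the counts of a library. Totals range from 27217899 to 33788024 per library, so a count of 0 allows up to 3 counts, or 0.0888 to 0.110 CPM, which covers counting error only. No library was left out.

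Samples were grouped by line, day and shRNA as the labels give them. The gene tests, the list tests within tables, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The list test over 16 libraries and 5 tests of explanations were chosen afterwards. Each table was fitted on its own in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10, TMM normalisation, glmQLFit and the two-sided quasi-likelihood F-test, with Benjamini-Hochberg adjustment over the tested genes and calls at an adjusted p under 0.05. The standard error is the absolute log2 fold change over the square root of F. One further fit of all 16 libraries with 8 group means gave the mean of the 4 changes, the Jurkat minus 6T-CEM difference and the difference between days in each line. CPM are scaled by TMM. A fold against a group at 0 was computed against a floor of 3 counts per library and written as a lower bound. Principal components were computed on log2 CPM of 15981 genes. Replicate numbers were not used as pairs, since the deviations of equal numbers from their group means correlated across genes at 0.023, 0.115, 0.104 and 0.009 in the 4 tables, and genes are not independent replicates.

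The rule for named genes took SH2D1A and CHI3L2 in every comparison. In each single comparison it took the 10 largest rises and the 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and both libraries of an arm above both of the other. For the mean of the 4 changes it took 10 and 10 with the same sign in all 4, for each difference 5 and 5, for each list up to 4 members with the lowest adjusted p, and among genes called in all 4 comparisons the 10 with the largest mean absolute change. BCL3 in Jurkat at day 10, RAG2, B2M in the line difference and other list members outside these limits were named after their values had been seen.

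The 28 gene lists hold 854 genes, of which 812 are in the tables. They are SLAM receptors and partners, T cell receptor signalling, chitinase family, ERK and immediate early targets, NF-kB targets, STAT5 and cytokine targets, NOTCH targets, T-ALL and thymocyte identity, MYC targets, S phase, G2/M, histones, p53 targets, BCL2 family, ATF4 stress response, heat shock and unfolded protein, cholesterol synthesis, glycolysis and hypoxia, respiratory chain, ribosomal proteins, mitochondrially encoded genes, interferon response, effector T cell genes, HLA class I and II, and markers of B cells, myeloid cells, epithelial and packaging cells, and erythroid cells. CHI3L2 is in the title of the series, so the chitinase list is not independent evidence of its direction. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With an estimated correlation camera takes its degrees of freedom from the libraries of the fit. These are few in a table of 4, so that test had little power in the single comparisons. The fry test of limma asks whether the members move one way on balance and compares a list with no other genes.

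The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, a filter of 10 counts in every library of a group, the replicate number as a block, all 16 libraries in the fit, a 2-fold threshold, and each library left out in turn. When a library is left out, the lone library of its arm is assumed to vary like the other groups. In 1 run the parametric dispersion trend of DESeq2 did not capture the data and the tool replaced it by a local regression. The procedure was tested on simulated data with the spread of these libraries. It recovered 62.6, 65.6, 42.7 and 66.3% of 2-fold changes in Jurkat day 8, Jurkat day 10, 6T-CEM day 5 and 6T-CEM day 10, and 40.6, 41, 10.1 and 51% of 1.5-fold changes. Of its calls there, 14.4, 11.9, 15 and 19.6% were false, above the nominal 5%. Only 195 or 196 genes per table were changed in the simulation, fewer than the 412 to 2752 called in the real tables. The shares recovered and false depend on that number, so they cannot be carried over to the real calls. Words of 7 bases in 3' UTRs were scored with a z over the mean of the 4 changes, in 13987 genes and 16270 words. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the word tests and plots.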

Results

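Messenger RNA was profiled by sequencing in Jurkat and 6T-CEM, 2 established human T-cell acute lymphoblastic leukaemia (T-ALL) lines, carrying a control short hairpin RNA (sh-NC) or one directed against SH2D1A (sh-SH2D1A). Jurkat was sampled at days 8 and 10 and 6T-CEM at days 5 and 10. The labels do not give the event from which the days are counted. Each line, day and shRNA had 2 libraries, which made 16 libraries in 8 groups, and each of the 4 comparisons had sh-NC libraries of its own. Total counts were 31645599 and 33788024 in the Jurkat day 8 sh-NC libraries and 31400085 and 28586944 in its sh-SH2D1A libraries, and at day 10 29469370 and 29026797 with sh-NC, 30838474 and 29171232 with sh-SH2D1A. In 6T-CEM they were 29838963 and 27942231 with sh-NC and 28972395 and 27217899 with sh-SH2D1A at day 5, and at day 10 28836423 and 31064535 with sh-NC, 30921714 and 31876720 with sh-SH2D1A. The first principal component held 56.0% of the variance and separated the lines. The second, with 20.75%, separated the days of 6T-CEM in both arms, between -36.12 and -11.77 at day 5 and between 32.75 and 46.28 at day 10. The third, with 6.04%, separated the arms, with all sh-SH2D1A libraries between 3.63 and 25.7 and all sh-NC libraries between -17.7 and -5.70. The libraries of 6T-CEM day 5 sh-SH2D1A differed from each other more than any other pair, with a chi-square per degree of freedom of 24.6 against 5.01 to 10.2, and 2 libraries do not show which is the unusual one. Mitochondrial genes took 7.98% of the counts in replicate 1 and 9.19% in replicate 2, against 7.44% and 7.63% in the day 5 sh-NC libraries. Fold changes below are log2 of sh-SH2D1A over sh-NC with their standard error, from 2 libraries per arm, and levels are TMM-scaled CPM as mean ± SD with n = 2.

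SH2D1A encodes SAP, a small adaptor protein that binds the tails of SLAM family receptors, and CHI3L2 encodes a secreted chitinase-like protein. The comparisons ask whether lowering SH2D1A lowers CHI3L2, as the title of the series states, and which other genes change. SH2D1A (ENSG00000183918, chromosome X, 124227868 to 124373197, hg38) fell in all 4 comparisons by edgeR. In Jurkat at day 8 it went from 168 ± 8.02 CPM with sh-NC to 51.1 ± 3.18 with sh-SH2D1A, a log2 change of -1.72 ± 0.07 (adjusted p = 3e-05), and at day 10 from 187 ± 19.3 to 61.9 ± 3.54, or -1.60 ± 0.10 (adjusted p = 6.3e-05). In 6T-CEM at day 5 it went from 192 ± 7.30 to 58.6 ± 5.06, or -1.71 ± 0.12 (adjusted p = 0.00191), and at day 10 from 161 ± 1.48 to 80.6 ± 4.67, or -1.0 ± 0.05 (adjusted p = 1.14e-05). CHI3L2 (ENSG00000064886, chromosome 1, 111200771 to 111243440) was 1202 ± 46.3 CPM in Jurkat sh-NC at day 8 and 387 ± 10 with sh-SH2D1A, a change of -1.64 ± 0.05 (adjusted p = 1.61e-05). At day 10 it was 1811 ± 26.2 and 713 ± 5.96, or -1.35 ± 0.07 (adjusted p = 2.52e-05). CHI3L2 was lower in 6T-CEM to begin with, at 339 ± 5.61 CPM at day 5 and 213 ± 3.0 at day 10. With sh-SH2D1A it went to 122 ± 11.2, or -1.47 ± 0.12 (adjusted p = 0.00191), and to 112 ± 0.0624, or -0.93 ± 0.03 (adjusted p = 4.22e-06). In every comparison both sh-SH2D1A libraries were below both sh-NC libraries for both genes. With no filter on low counts the Jurkat day 10 calls of both genes were lost, at changes of -1.60 and -1.35 and an adjusted p = 0.139 from edgeR. The span of SH2D1A overlaps STAG2 on the same strand and that of CHI3L2 overlaps DENND2D on the other. DENND2D, which was rarer than CHI3L2, changed by -0.54 ± 0.11 and -0.54 ± 0.12 in Jurkat at days 8 and 10, and in 6T-CEM by -0.45 ± 0.24 and -0.24 ± 0.18 at days 5 and 10 (not passed). STAG2 changed by -0.21 ± 0.05 in Jurkat at day 8 and -0.16 ± 0.03 in 6T-CEM at day 10, and by -0.23 ± 0.09 and -0.44 ± 0.13 in Jurkat at day 10 and 6T-CEM at day 5 (not passed). The p-values measure only the spread between these libraries, and the labels do not say whether the 2 libraries of a group are separate cultures.

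**Figure D1:**
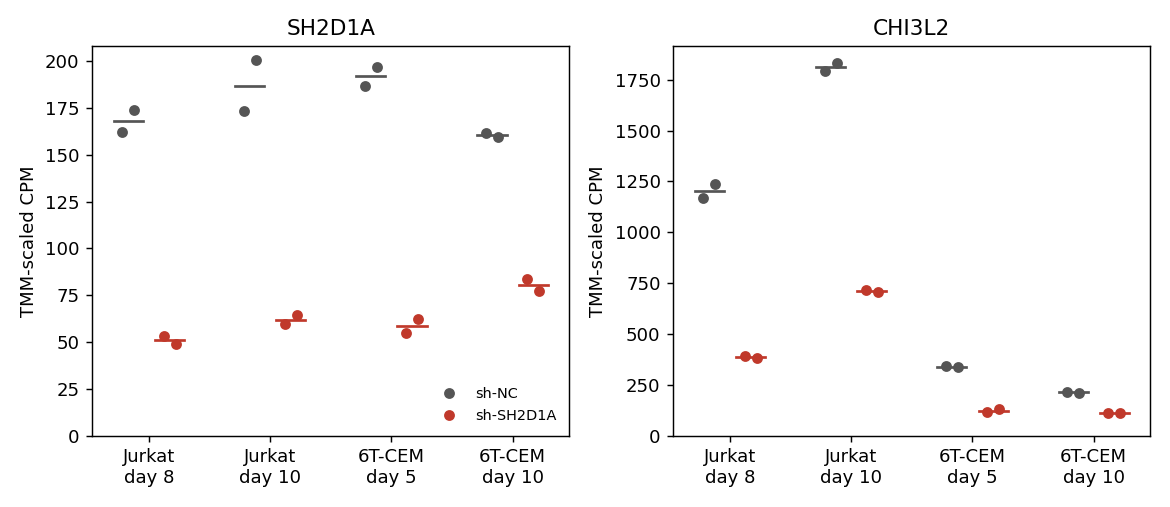
TMM-scaled CPM of SH2D1A (left) and CHI3L2 (right) by line and day, one point per library and a bar for the mean of the 2 libraries, grey for sh-NC and red for sh-SH2D1A. In each comparison both sh-SH2D1A points lie below both sh-NC points, and CHI3L2 with sh-NC lies at 1202 and 1811 CPM in Jurkat and at 339 and 213 CPM in 6T-CEM.

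In Jurkat at day 8, genes of glycolysis, cholesterol synthesis, NF-kB and T cell receptor signalling fell with sh-SH2D1A, and MYC targets rose. edgeR called 1008 genes higher and 1373 lower of 19266 tested, and 211 of them changed at least 2-fold, 105 up and 106 down. Glycolysis and hypoxia genes had the lowest camera p of the lists: 26 of 35 fell and 0 rose, or 29 and 0 adjusted over the list alone (camera adjusted p = 3.95e-12, or adjusted p = 0.228 with an estimated correlation). The log2 change was -1.16 ± 0.06 for ALDOC, an aldolase, -1.41 ± 0.09 for PFKFB4, which sets the flux through phosphofructokinase, -0.91 ± 0.06 for BNIP3 and -0.87 ± 0.07 for PDK1, which holds pyruvate back from the mitochondria. Among cholesterol synthesis genes 19 of 28 fell and 1 rose, or 23 and 1 adjusted over the list alone (camera adjusted p = 1.56e-08, or adjusted p = 0.217 with an estimated correlation). They included FADS2 at -0.66 ± 0.05 and SCD at -0.50 ± 0.05, desaturases of fatty acids that the list holds beside the sterol genes. INSIG1, a brake on sterol synthesis, changed by -0.59 ± 0.05. Of NF-kB targets 11 of 17 fell and 0 rose, or 13 and 0 adjusted over the list alone (camera adjusted p = 3.78e-06, or adjusted p = 0.217 with an estimated correlation). NFKB1, which encodes the p105 precursor of p50, changed by -1.14 ± 0.07 and IL32, a cytokine gene, by -0.90 ± 0.05. In the list of ERK and immediate early targets 10 of 28 fell and 1 rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000105, or adjusted p = 0.217 with an estimated correlation). The activation marker CD69 changed by -1.29 ± 0.11, the transcription factors EGR1 by -0.90 ± 0.07 and ETV5 by -1.44 ± 0.12, and MYC by 0.47 ± 0.05.

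Genes of the T cell receptor apparatus were lower in the same cells: 15 of 32 fell and 1 rose, or 20 and 1 adjusted over the list alone (camera adjusted p = 2.74e-05, or adjusted p = 0.217 with an estimated correlation). The surface receptors CD2, CD28 and CD5 changed by -0.77 ± 0.07, -0.55 ± 0.05 and -0.58 ± 0.06. For SLAM receptors and their partners 7 of 17 fell and 0 rose, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.000588, or adjusted p = 0.217 with an estimated correlation), with CD48 at -0.95 ± 0.10, SLAMF6 at -0.78 ± 0.10 and CD84 at -0.64 ± 0.09. In the HLA list 6 of 15 fell and 0 rose, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.00106, or adjusted p = 0.217 with an estimated correlation). These were class I genes, such as HLA-B at -0.99 ± 0.06, HLA-E at -1.27 ± 0.12 and B2M, their light chain, at -0.57 ± 0.06. Of p53 targets 9 of 25 fell and 2 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00118, or adjusted p = 0.217 with an estimated correlation). DDB2, a DNA repair gene, changed by -1.0 ± 0.05 and PMAIP1, a pro-apoptotic BCL2 family gene, by -0.80 ± 0.08. In the chitinase family list, which holds the title gene CHI3L2 and so is no independent evidence, CHI3L2 alone of 4 measured genes passed over all genes, and 3 fell adjusted over the list alone (camera adjusted p = 0.00466, or adjusted p = 0.228 with an estimated correlation). MYC targets, genes of ribosome assembly and nucleotide supply, went the other way: 28 of 39 rose and 2 fell, or 31 and 2 adjusted over the list alone (camera adjusted p = 4.91e-11, or adjusted p = 0.217 with an estimated correlation). MYBBP1A, RRP12 and POLR1A changed by 0.51 ± 0.05, 0.62 ± 0.07 and 0.54 ± 0.06. Of heat shock and unfolded protein genes 10 of 26 rose and 1 fell, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.00737, or adjusted p = 0.228 with an estimated correlation), with the chaperones HSPA5 at 0.66 ± 0.05 and HSPA8 at 0.56 ± 0.05. Without sh-NC replicate 1 this list had a camera adjusted p = 0.0625.

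Among the largest rises at day 8, ELN, which encodes elastin, changed by 2.85 ± 0.33, MFAP4, a matrix protein gene, by 1.80 ± 0.12, VCAN, which encodes versican, by 1.80 ± 0.38, and TNFRSF4, which encodes the receptor OX40, by 1.69 ± 0.24. RAG1 (chromosome 11, 36510709 to 36593156), which encodes the recombinase of antigen receptor genes, went from 11.8 ± 1.80 to 41.9 ± 1.40 CPM, or 1.83 ± 0.12 by edgeR (adjusted p = 0.000337). GATM, ANKRD63, SHISA8 and DAGLA changed by 1.78 ± 0.31, 1.73 ± 0.36, 1.73 ± 0.30 and 1.69 ± 0.24 from levels under 2 CPM. TBCA, a tubulin folding cofactor on chromosome 5 (77691166 to 77868780), went from 110 ± 4.32 to 29.5 ± 0.443 CPM, or -1.90 ± 0.06 (edgeR adjusted p = 1.61e-05). BCL3, a nuclear partner of p50, changed by -1.90 ± 0.40, ARHGAP29 by -2.22 ± 0.31 and HOXA4 by -2.06 ± 0.37. Read-through genes, which are annotated across 2 neighbouring genes and share exons with both, filled other places among the largest changes. BIVM-ERCC5 had 2460 and 2714 counts with sh-NC and 0 with sh-SH2D1A, at least 799-fold lower against a floor of 3 counts per library, and SYS1-DBNDD2 was at least 35.5-fold lower. CORO7-PAM16 changed by -5.94 ± 0.64 and SENP3-EIF4A1 by 3.74 ± 0.96, with sh-SH2D1A libraries at 4.76 and 41.0 CPM. TEN1, CDRT4 and BMS1P4-AGAP5, which also overlap neighbours on their strand, changed by -2.79 ± 0.40, -2.25 ± 0.55 and -1.92 ± 0.29. Single libraries decided several of these calls. Those of GATM, ANKRD63, SHISA8, VCAN, BCL3 and CDRT4 were lost without either sh-SH2D1A library, that of HOXA4 without sh-SH2D1A replicate 1 and that of SENP3-EIF4A1 without sh-SH2D1A replicate 2 or sh-NC replicate 2. Those of VCAN and BCL3 were also lost without sh-NC replicate 2, and that of CDRT4 without sh-NC replicate 1. The number of calls fell to 835 without sh-SH2D1A replicate 1, to 633 without replicate 2, to 873 with no filter on low counts and to 1323 with all 16 libraries in the fit.

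At day 10 in Jurkat the lipid, glycolysis and NF-kB genes were lower again, together with HLA class I genes, and the recombinase genes RAG1 and RAG2 were higher. edgeR called 240 genes higher and 481 lower of 19079, and 163 of these changed at least 2-fold. Cholesterol synthesis genes had the lowest camera p of the lists: 14 of 28 fell and 0 rose, or 24 and 0 adjusted over the list alone (camera adjusted p = 2.34e-11, or adjusted p = 0.309 with an estimated correlation). FADS2 and SCD changed by -0.69 ± 0.07 and -0.53 ± 0.07. For glycolysis and hypoxia 10 of 34 fell and 0 rose, or 23 and 0 adjusted over the list alone (camera adjusted p = 7.59e-09, or adjusted p = 0.324 with an estimated correlation), with ALDOC at -1.24 ± 0.09, the glucose transporter SLC2A3 at -1.07 ± 0.13 and VEGFA, an angiogenic factor, at -0.71 ± 0.09. Of NF-kB targets 5 of 17 fell and 0 rose, or 8 and 0 adjusted over the list alone (camera adjusted p = 3.27e-07, or adjusted p = 0.324 with an estimated correlation), with NFKB1 at -1.41 ± 0.10 and BCL3 at -1.68 ± 0.32. ERK and immediate early targets gave 7 lower and 1 higher of 28, or 10 and 1 adjusted over the list alone (camera adjusted p = 4.25e-06, or adjusted p = 0.309 with an estimated correlation). ETV5 and EGR1 changed by -1.36 ± 0.13 and -0.79 ± 0.09, and the member that rose was MYC at 0.74 ± 0.08. In the HLA list 7 of 14 fell and 0 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 1e-05, or adjusted p = 0.309 with an estimated correlation). HLA-B and NLRC5, the activator of class I transcription, changed by -1.17 ± 0.10 and -0.76 ± 0.10. T cell receptor genes counted 5 lower and 1 higher of 32, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00207, or adjusted p = 0.326 with an estimated correlation). SLAM receptors and partners counted 4 lower and 0 higher of 17, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0124, or adjusted p = 0.324 with an estimated correlation). Of p53 targets 5 of 25 fell and 0 rose, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.000142, or adjusted p = 0.309 with an estimated correlation), with DDB2 at -0.75 ± 0.08 and BAX at -0.76 ± 0.13. MYC targets were again higher as a list, and 4 of 39 rose and 1 fell, or 15 and 2 adjusted over the list alone (camera adjusted p = 6.27e-06, or adjusted p = 0.324 with an estimated correlation). The spermidine synthase gene SRM fell within it, at -0.50 ± 0.10.

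Stress genes were lower as lists at day 10. For ATF4 targets 2 of 28 fell and 0 rose, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.00333, or adjusted p = 0.326 with an estimated correlation), and for heat shock and unfolded protein genes 4 of 26 fell and 1 rose, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.0341, or adjusted p = 0.657 with an estimated correlation). The heat shock call was lost without sh-NC replicate 1 (camera adjusted p = 0.0557), sh-NC replicate 2 (adjusted p = 0.0862) or sh-SH2D1A replicate 2 (adjusted p = 0.165). XBP1, a transcription factor of the unfolded protein response, went from 67.2 ± 2.0 to 15.2 ± 5.72 CPM, or -2.14 ± 0.19 by edgeR (adjusted p = 0.000315). S phase genes were lower as a list with a single member past the threshold, CCNE2, which encodes cyclin E2, at -0.51 ± 0.10 (camera adjusted p = 0.00214, or adjusted p = 0.324 with an estimated correlation). RAG1 changed by 2.11 ± 0.14 and RAG2, whose span overlaps RAG1 on the other strand, by 1.57 ± 0.15. IFTAP, whose span overlaps RAG2 on the other strand, changed by 2.56 ± 0.41. ELN and VCAN changed by 3.47 ± 0.27 and 2.94 ± 0.30, and CPA4, a carboxypeptidase gene, DCLK3, a kinase gene, and NIBAN1 by 2.13 ± 0.24, 2.47 ± 0.29 and 2.16 ± 0.38. TRIM22, an interferon-induced ubiquitin ligase gene, changed by -1.88 ± 0.24, DSCAML1, a cell adhesion gene, by -2.17 ± 0.26 and GPR84, a receptor for medium-chain fatty acids, by -1.89 ± 0.35. CTBP2, ZBTB7C and PCDHGB7 changed by 2.04 ± 0.46, 1.87 ± 0.37 and 2.14 ± 0.42, and TNRC6C-AS1 by -1.79 ± 0.35. On their own strand, PCDHGB7 overlaps other PCDHG genes, TNRC6C-AS1 overlaps TMC6 and DSCAML1 overlaps FXYD2. The sh-SH2D1A libraries of PCDHGB7 were at 1.76 and 3.48 CPM. Other genes with close copies or overlapping neighbours made up the rest of the largest falls. RPS10-NUDT3 and CDRT4 changed by -3.77 ± 0.90 and -2.90 ± 0.53, the pseudogene GAPDHP62 by -2.11 ± 0.40, GOLGA8S by -3.14 ± 0.45, and BEST1, which overlaps FTH1 on the other strand, by -3.68 ± 0.32. Calls of CDRT4, RPS10-NUDT3, TNRC6C-AS1, ZBTB7C and CTBP2 were lost without sh-NC replicate 2, and those of GAPDHP62, GPR84 and PCDHGB7 without sh-NC replicate 1. CTBP2 was also lost without sh-SH2D1A replicate 1 and PCDHGB7 without sh-SH2D1A replicate 2. With no filter on low counts edgeR called 0 genes here, with 3533 at an unadjusted p under 0.05, while DESeq2 with the filter called 1054.

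In 6T-CEM at day 5 cholesterol synthesis, glycolysis and ERK target genes were lower as lists with sh-SH2D1A. Of 21 effector T cell genes 2 were called higher, EOMES and GZMH, and 1 lower. edgeR called 118 genes higher and 294 lower of 19482, and 178 changed at least 2-fold. The count rose to 2139 without sh-SH2D1A replicate 2, the library with the high mitochondrial share, to 2865 without replicate 1, to 1118 with DESeq2 and to 3108 with all 16 libraries in the fit. Of cholesterol synthesis genes 8 of 29 fell and 0 rose, or 16 and 0 adjusted over the list alone (camera adjusted p = 3.01e-07, or adjusted p = 0.373 with an estimated correlation). INSIG1 and FADS2 changed by -1.07 ± 0.12 and -0.91 ± 0.12. Glycolysis and hypoxia counted 5 lower and 0 higher of 35, or 19 and 0 adjusted over the list alone (camera adjusted p = 3e-08, or adjusted p = 0.373 with an estimated correlation), with hexokinase 2 (HK2) at -0.90 ± 0.12 and SLC2A3 at -1.21 ± 0.21. ERK and immediate early targets counted 4 lower and 0 higher of 24, or 9 and 1 adjusted over the list alone (camera adjusted p = 7.83e-05, or adjusted p = 0.373 with an estimated correlation). They were ETV5 at -1.60 ± 0.22, CD69 at -1.39 ± 0.21 and the ERK pathway inhibitors SPRED1 at -0.89 ± 0.15 and SPRED2 at -1.18 ± 0.16. NF-kB targets counted 2 lower of 17, TNFAIP3, a feedback inhibitor of NF-kB, at -0.98 ± 0.12 and NFKB1 at -1.22 ± 0.16, or 5 adjusted over the list alone (camera adjusted p = 9.24e-05, or adjusted p = 0.373 with an estimated correlation). Cell cycle lists were lower too. S phase had 2 of 41 lower, CCNE2 at -1.02 ± 0.15 and E2F8 at -0.66 ± 0.13, or 9 adjusted over the list alone (camera adjusted p = 9.24e-05, or adjusted p = 0.497 with an estimated correlation). G2/M had 1 of 50 lower, ECT2, a gene of cell division, at -0.68 ± 0.12 (camera adjusted p = 0.00137, or adjusted p = 0.586 with an estimated correlation), and the call was lost without sh-NC replicate 2 (adjusted p = 0.0926) or sh-SH2D1A replicate 1 (adjusted p = 0.191). p53 targets had 1 of 25 lower, DDB2 at -0.96 ± 0.13, or 3 adjusted over the list alone (camera adjusted p = 0.0294, or adjusted p = 0.426 with an estimated correlation). That call was lost without sh-NC replicate 2 (camera adjusted p = 0.152) or sh-SH2D1A replicate 2 (adjusted p = 0.177).

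Effector T cell genes were higher as a list, with 2 of 21 up and 1 down, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.0136, or adjusted p = 0.373 with an estimated correlation). EOMES, a transcription factor of cytotoxic lymphocytes, changed by 1.92 ± 0.14 and the granzyme gene GZMH by 2.93 ± 0.60. GZMH started near the floor of 3 counts, at 0.249 ± 0.162 CPM with sh-NC. Without sh-SH2D1A replicate 2 this list had an adjusted p = 0.0752. The calls of 4 further lists rested on single libraries at day 5. Interferon response genes had a median of 0.18 with 0 of 42 past the threshold and 1 up adjusted over the list alone (camera adjusted p = 0.0269, or adjusted p = 0.373 with an estimated correlation). MYC targets had a median of 0.13 with SRM, at -0.90 ± 0.14, the only member past it, lower (camera adjusted p = 0.0269, or adjusted p = 0.373 with an estimated correlation). Ribosomal proteins had a median of 0.09 with 0 of 71 past it (camera adjusted p = 0.0294, or adjusted p = 0.378 with an estimated correlation). Each of these 3 calls was lost without sh-NC replicate 1 (camera adjusted p = 0.103, 0.297 and 0.434), sh-NC replicate 2 (0.0842, 0.158 and 0.152) or sh-SH2D1A replicate 1 (0.0561, 0.145 and 0.071). Mitochondrially encoded genes had 2 of 13 up, MT-ATP8 at 0.78 ± 0.15 and MT-ND3 at 0.58 ± 0.12, or 6 adjusted over the list alone (camera adjusted p = 0.015, or adjusted p = 0.64 with an estimated correlation). Their call was lost without sh-SH2D1A replicate 2 (camera adjusted p = 0.243) or either sh-NC library (adjusted p = 0.144 and 0.0842). The largest rises were CCR1, a chemokine receptor gene, at 3.53 ± 0.60, CFTR, a chloride channel gene, at 3.22 ± 0.68, PCDH10, a protocadherin gene, at 2.60 ± 0.24, TC2N at 2.52 ± 0.32 and SCG2, a secretogranin gene, at 2.30 ± 0.27. CCR1 and CFTR started near the floor of 3 counts, at 0.175 ± 0.00954 and 0.232 ± 0.186 CPM with sh-NC. SCUBE1, MXRA8, SPATA3-AS1 and USP3-AS1 changed by 2.43 ± 0.52, 2.36 ± 0.50, 2.62 ± 0.45 and 2.26 ± 0.37. Among the largest falls, GNB4, a G protein subunit gene, changed by -1.95 ± 0.16, IL1RAP, a co-receptor for interleukin 1, by -1.77 ± 0.20, CDK2AP1 by -1.71 ± 0.17 and ZBTB16, which encodes the transcription factor PLZF, by -1.70 ± 0.27. ATP4A, C2orf48, the T cell receptor segment TRBV28 and the pseudogene SERPINH1P1 changed by -1.72 ± 0.34, -1.70 ± 0.27, -1.69 ± 0.22 and -2.44 ± 0.41. The read-through gene ATP5MF-PTCD1 was at 0 with sh-SH2D1A and at least 21.4-fold lower. Calls of ATP4A and ATP5MF-PTCD1 were lost without sh-NC replicate 2, SCUBE1 without sh-NC replicate 1, MXRA8 without sh-SH2D1A replicate 1 and CFTR without sh-SH2D1A replicate 2.

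In 6T-CEM at day 10 HLA and cytotoxic effector genes were higher with sh-SH2D1A, and glycolysis genes and the list of T-ALL and thymocyte identity were lower. edgeR called 1296 genes higher and 1456 lower of 19610, and 303 changed at least 2-fold. In the HLA list 7 of 16 rose and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00773, or adjusted p = 0.508 with an estimated correlation). HLA-B, HLA-C and NLRC5 changed by 0.71 ± 0.04, 0.58 ± 0.05 and 0.82 ± 0.06. Effector T cell genes counted 7 up and 2 down of 24, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.026, or adjusted p = 0.508 with an estimated correlation). EOMES changed by 2.18 ± 0.04 and the granzyme genes GZMM and GZMH by 2.0 ± 0.13 and 2.60 ± 0.28. Without sh-SH2D1A replicate 2 the HLA list had a camera adjusted p = 0.0557 and the effector list one of 0.0883, and with the replicate number as a block 0.0679 and 0.153. In the list of T-ALL and thymocyte identity 15 of 33 fell and 3 rose, or 17 and 5 adjusted over the list alone (camera adjusted p = 0.00246, or adjusted p = 0.508 with an estimated correlation). MYB, TOX and GATA3 changed by -0.63 ± 0.03, -0.67 ± 0.04 and -0.66 ± 0.04, and RAG1 by 1.35 ± 0.04. Of glycolysis and hypoxia genes 17 of 35 fell and 1 rose, or 20 and 1 adjusted over the list alone (camera adjusted p = 0.00054, or adjusted p = 0.508 with an estimated correlation). Their values included LDHA, lactate dehydrogenase, at -0.44 ± 0.03, GAPDH at -0.24 ± 0.02, ALDOC at -1.36 ± 0.11 and PDK1 at -0.87 ± 0.09. Cholesterol synthesis genes had 6 of 29 lower and 3 higher, or 7 and 3 adjusted over the list alone, with no shift as a list by camera (adjusted p = 0.259) and a lower list by fry (adjusted p = 0.0178). INSIG1 and FADS2 changed by -0.78 ± 0.03 and -0.57 ± 0.03.

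Among the largest rises at this day, KLRD1, which encodes the killer receptor CD94, changed by 3.57 ± 0.47, SLAMF7, a SLAM family receptor gene, by 2.68 ± 0.24, from 1.05 ± 0.196 to 6.75 ± 0.0557 CPM, and TGFBR3, a co-receptor for TGF-beta, by 2.44 ± 0.36. KLRD1 started near the floor of 3 counts, at 0.1535 ± 0.0791 CPM with sh-NC. RAPH1, which encodes lamellipodin, an actin regulator, changed by 3.22 ± 0.30, SAMD3 by 3.09 ± 0.32, B3GALT5, a glycosyltransferase gene, by 2.53 ± 0.23 and TC2N by 2.44 ± 0.20. Among the falls, ZBTB16 went from 12.1 ± 1.20 to 1.71 ± 0.171 CPM, or -2.81 ± 0.19 (edgeR adjusted p = 6.79e-05), and ANXA1, which encodes the anti-inflammatory protein annexin A1, from 10.2 ± 0.367 to 1.49 ± 0.0575 CPM, or -2.77 ± 0.19 (edgeR adjusted p = 6.81e-05). ADCYAP1, which encodes the neuropeptide PACAP, changed by -2.65 ± 0.23, CA9, the hypoxia-induced carbonic anhydrase gene, by -2.54 ± 0.33, and CHST1, GPR17 and SLC6A20 by -2.43 ± 0.40, -2.27 ± 0.28 and -2.25 ± 0.40. Read-through genes and close copies again took places on both sides. BIVM-ERCC5, absent with sh-SH2D1A in Jurkat at day 8, had 784 and 1357 counts with sh-SH2D1A here and 0 with sh-NC, at least 334-fold higher. SENP3-EIF4A1 and PPAN-P2RY11 changed by -3.38 ± 0.25 and -3.25 ± 0.84, the pseudogene PVRIG2P by -4.00 ± 0.58 and UPK3BL1, which has close copies, by 2.40 ± 0.59, a call lost without sh-SH2D1A replicate 2. The number of calls fell to 1099 with no filter on low counts and to 916 with all 16 libraries in the fit.

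**Figure D2:**
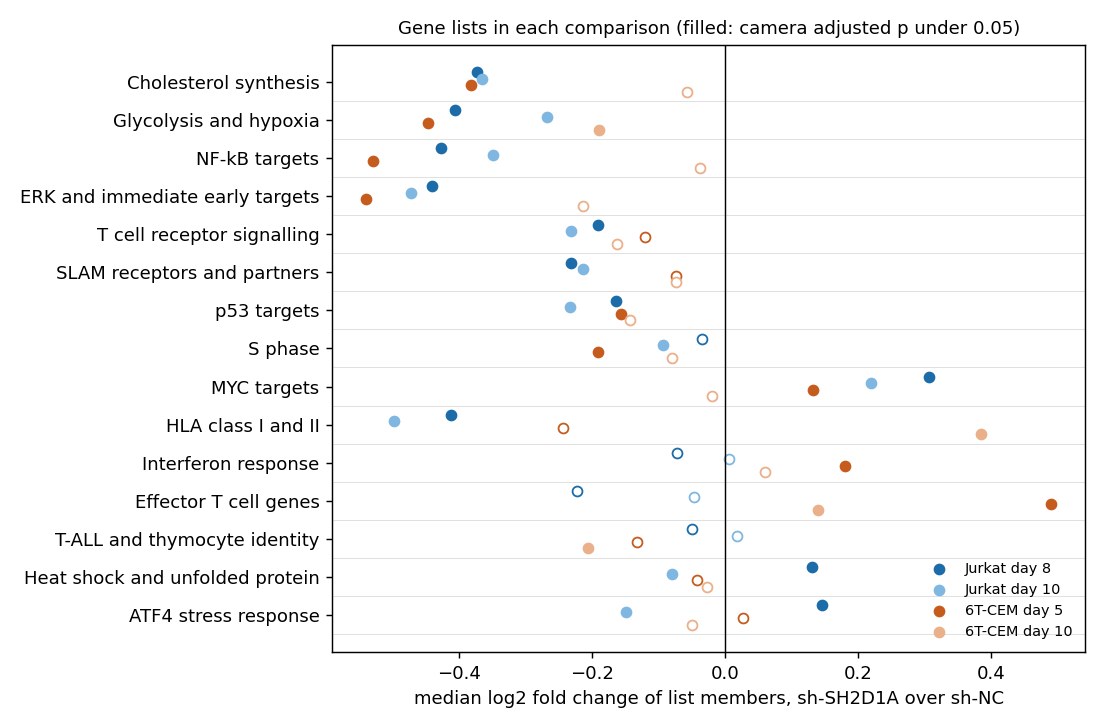
Median log2 fold change of the members of 15 gene lists (horizontal axis) in the 4 comparisons, by colour, filled where camera with a preset correlation of 0.01 gave an adjusted p under 0.05 and open elsewhere. Glycolysis and hypoxia is filled and lies left of 0 in all 4, and HLA class I and II lies left of 0 in Jurkat and right of 0 in 6T-CEM at day 10. None of the 43 filled points of all 28 lists passed with an estimated correlation, a test with little power in tables of 4 libraries.

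SH2D1A and CHI3L2 fell and RAG1 rose in all 4 comparisons. Of 17521 genes tested in every comparison, 21 rose and 116 fell in all 4 by edgeR, against 0.00553 and 0.0491 for independent lists. Those expected numbers treat all genes as equally likely to be called, which level and spread make untrue, so they are too low a baseline. In 128 combinations of relabelled libraries the highest number called in all 4 was 0. Relabelled tables called at most 5 genes each, so that 0 says little about the overlap. Among the 10 with the largest mean change, RAG1 changed by 1.83 and 2.11 in Jurkat and 0.91 and 1.35 in 6T-CEM. MFAP4 changed by 1.80 and 1.11 in Jurkat and 1.69 and 0.89 in 6T-CEM, and STRA6, a retinol transporter gene, by 1.36 and 1.39 in Jurkat and 1.44 and 1.1 in 6T-CEM. Of those that fell, ADCYAP1 changed by -1.40 and -1.15 in Jurkat and -1.52 and -2.65 in 6T-CEM, and TBCA by -1.90 and -1.49 in Jurkat and -1.46 and -1.55 in 6T-CEM. ETV5, a transcription factor downstream of ERK, changed by -1.44 and -1.36 in Jurkat and -1.60 and -1.42 in 6T-CEM, BHLHE40, a transcription factor of activated T cells, by -1.71 and -1.46 in Jurkat and -1.33 and -0.99 in 6T-CEM, and SEMA4A, a semaphorin gene, by -1.32 and -1.17 in Jurkat and -1.56 and -1.29 in 6T-CEM. Of the genes lower in all 4, 113 had an annotated 3' UTR, and 47 of these (41.6%) carried the 7-base word GGTTACA there, which occurs 1 time in SH2D1A, in the coding part of exon 2. The share was 7.20% over 13987 tested genes, and 12 carriers would be drawn at the 3' UTR lengths of the 113. GGTTACA was chosen out of 16270 words as the one whose carriers were lowest in these same changes. TBCA and NFKB1 are among the carriers, while CHI3L2, ADCYAP1, ETV5, BHLHE40 and SEMA4A are not. With no filter on low counts 0 genes were called in all 4, since none was called in Jurkat at day 10 there. With DESeq2 264 were called, with all 16 libraries in 1 fit 219, without either sh-NC library of 6T-CEM day 5 86 and 70, and without either sh-SH2D1A library of that day 216 and 213.

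**Figure D3:**
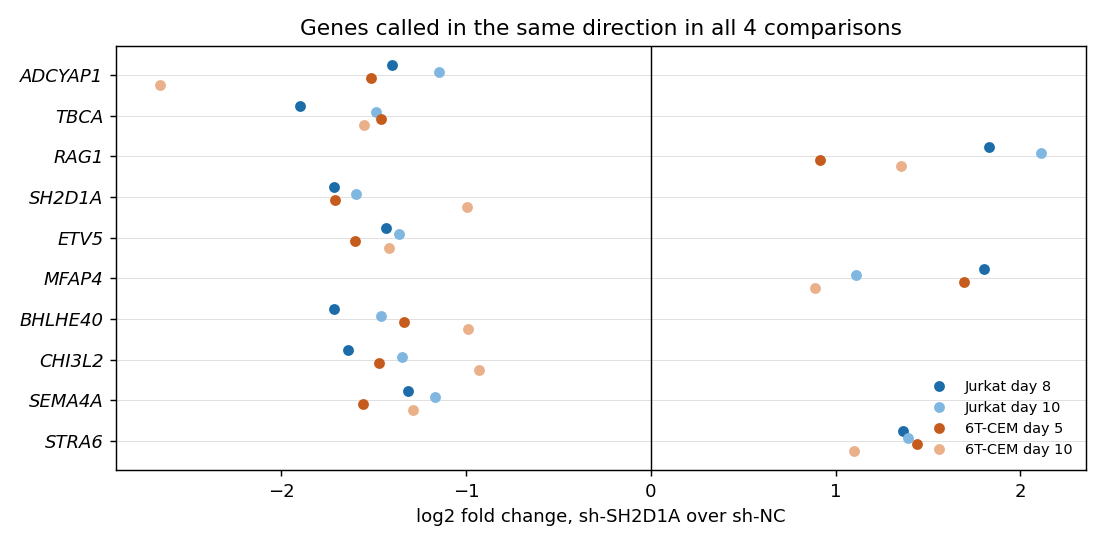
Log2 fold change of sh-SH2D1A over sh-NC (horizontal axis) for the 10 genes with a symbol and the largest mean change among those called in the same direction in all 4 comparisons, one point per comparison, coloured by line and day. RAG1, MFAP4 and STRA6 lie right of 0 in all 4, and the 7 others, with SH2D1A and CHI3L2 among them, lie left of 0.

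Averaged over the 4 comparisons in 1 fit of 16 libraries, edgeR called 2356 genes higher and 2707 lower of 22032, and 321 changed at least 2-fold. SH2D1A changed by -1.51 ± 0.05 (adjusted p = 1.21e-10) and CHI3L2 by -1.35 ± 0.03 (adjusted p = 7.49e-12). Of the genes that rose, RAG1, ELN, VCAN and CFTR changed by 1.55 ± 0.06, 2.17 ± 0.17, 1.66 ± 0.12 and 2.28 ± 0.32. SPATA3-AS1, TNFRSF4, IFTAP, CBLL1-AS1 and MFAP4 changed by 2.07 ± 0.21, 1.45 ± 0.28, 1.44 ± 0.23, 1.44 ± 0.25 and 1.37 ± 0.08, and TRPS1 by 2.47 ± 0.35, a value that rests on a Jurkat day 8 sh-NC group at 0 and is no bound. TRPS1 was at least 8.23-fold higher in that comparison. TNFRSF4 and CBLL1-AS1 were at 0.0511 and 0.0681 CPM with sh-NC in 6T-CEM at day 5, under the floor, and their averages rest in part on that group. CBLL1-AS1 passed in no single comparison and changed by 0.25 and 0.22 in Jurkat. TNFRSF4 passed in Jurkat at day 8 alone and changed by 0.01 in 6T-CEM at day 10. CFTR was near the floor with sh-NC in 6T-CEM, at 0.236 and 0.118 CPM. Of the falls below, CHST1 passed in 6T-CEM at day 10 alone. Among the falls, BCL3 changed by -1.74 ± 0.24, ZBTB16 by -1.71 ± 0.13, ADCYAP1 by -1.68 ± 0.07, ANXA1 by -1.64 ± 0.08, TBCA by -1.60 ± 0.06, CHST1 by -1.53 ± 0.22, XBP1 by -1.52 ± 0.24, ETV5 by -1.46 ± 0.08 and BHLHE40 by -1.38 ± 0.09. Lists were also tested over the 16 libraries, a test chosen after the data had been examined, and 13 of 28 passed with the preset correlation, 7 of them with an estimated one too. In cholesterol synthesis 22 of 29 fell and 0 rose (camera adjusted p = 4.03e-13, or adjusted p = 0.00072 with an estimated correlation), and glycolysis and hypoxia 27 of 36 fell and 0 rose (camera adjusted p = 5.24e-17, or adjusted p = 0.00902 with an estimated correlation). In T cell receptor signalling 18 of 32 fell and 3 rose (camera adjusted p = 0.000155, or adjusted p = 0.00902 with an estimated correlation), ERK and immediate early targets 14 of 29 fell and 3 rose (camera adjusted p = 8.21e-06, or adjusted p = 0.00902 with an estimated correlation), and NF-kB targets 11 of 18 fell and 0 rose (camera adjusted p = 9.59e-08, or adjusted p = 0.014 with an estimated correlation). For p53 targets 11 of 25 fell and 1 rose (camera adjusted p = 0.00015, or adjusted p = 0.0125 with an estimated correlation). MYC targets went up, where 26 of 39 rose and 2 fell (camera adjusted p = 3.61e-08, or adjusted p = 0.00848 with an estimated correlation). Of these 7 lists only glycolysis and hypoxia passed by camera in each of the 4 comparisons, and by fry it did not pass in 6T-CEM at day 5 (adjusted p = 0.051). ERK, NF-kB, p53 and MYC targets did not pass by fry there either (adjusted p = 0.051, 0.0842, 0.101 and 0.118). T cell receptor signalling had 1 of 32 lower in 6T-CEM at day 5 (camera adjusted p = 0.172) and 7 higher and 10 lower at day 10 (camera adjusted p = 0.147), or 4 and 15 lower adjusted over the list alone, and was lower by fry at both days (adjusted p = 0.042 and 0.0226). MYC targets had 1 of 39 higher and 5 lower in 6T-CEM at day 10, with a median of -0.02 (camera adjusted p = 0.546, or adjusted p = 0.0226 by fry, downwards). No member of the cholesterol or glycolysis lists carried GGTTACA in its 3' UTR. NFKB1 in the NF-kB list, SLAMF6 in the SLAM list, and CD247, CD4, GRAP2 and VAV1 in the T cell receptor list did and were lower. Further lists passed with the preset correlation and are given by their median: SLAM receptors and partners at -0.06 (camera adjusted p = 0.0103, or adjusted p = 0.0647 with an estimated correlation). Chitinase family had -0.23 (camera adjusted p = 0.00908, or adjusted p = 0.0581 with an estimated correlation). S phase had -0.11 (camera adjusted p = 8.21e-06, or adjusted p = 0.0815 with an estimated correlation). G2/M had -0.06 (camera adjusted p = 0.0386, or adjusted p = 0.526 with an estimated correlation). Mitochondrially encoded genes had 0.13 (camera adjusted p = 0.0105, or adjusted p = 0.526 with an estimated correlation). HLA class I and II had -0.17 (camera adjusted p = 0.035, or adjusted p = 0.397 with an estimated correlation).

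The lines differed in how some immune genes responded. In the test of the Jurkat change minus the 6T-CEM change over 16 libraries, in which only day 10 is matched, edgeR called 266 genes higher and 152 lower of 22032. HLA class I genes fell in Jurkat, while in 6T-CEM the list had a median of -0.24 at day 5, with 0 of 15 past the threshold and 2 lower adjusted over the list alone, and several genes rose at day 10. HLA-B changed by -0.70 ± 0.17 at day 5 in 6T-CEM (edgeR adjusted p = 0.076). The difference between the lines, averaged over the days of each, was -1.07 ± 0.12 for HLA-B and -0.74 ± 0.08 for B2M. In the HLA list 6 of 16 genes differed (camera adjusted p = 3e-07, or adjusted p = 0.0571 with an estimated correlation). Interferon response genes differed the same way, 6 of 44, with GBP1 at -0.90 ± 0.11 and TRIM22 at -1.40 ± 0.28 (camera adjusted p = 7.28e-05, or adjusted p = 0.0119 with an estimated correlation). MYC targets had a higher change in Jurkat, 3 of 39 (camera adjusted p = 4.28e-09, or adjusted p = 0.0098 with an estimated correlation), and MYC itself differed by 0.57 ± 0.07. T-ALL and thymocyte identity genes also had a higher change in Jurkat, 7 of 35 (camera adjusted p = 0.000112, or adjusted p = 0.0571 with an estimated correlation), among them TCF7 at 0.56 ± 0.07, MYB at 0.56 ± 0.07 and RAG1 at 0.85 ± 0.11. For effector genes EOMES differed by -1.60 ± 0.12 and GZMM by -2.05 ± 0.35 (camera adjusted p = 1.34e-05, or adjusted p = 0.0504 with an estimated correlation). SH2D1A differed by -0.29 ± 0.09 (edgeR adjusted p = 0.121, or 0.0328 by DESeq2 and 0.0384 by edgeR without replicate 1 of 6T-CEM day 5 sh-SH2D1A) and CHI3L2 by -0.28 ± 0.06 (edgeR adjusted p = 0.0347), a larger fall in Jurkat for the latter, whose call was lost in 13 of the 16 fits without 1 library. TC2N, SCG2 and RAPH1 differed by -3.37 ± 0.37, -2.72 ± 0.36 and -2.23 ± 0.38, calls lost in none of them, with TC2N between 0.136 and 0.372 CPM in the Jurkat groups. The count of 418 ranged from 196 without replicate 1 of 6T-CEM day 10 sh-SH2D1A to 981 without replicate 2 of 6T-CEM day 5 sh-SH2D1A, and was 877 with DESeq2. Other lists differed with the preset correlation and are given by their median: SLAM receptors and partners at -0.10 (camera adjusted p = 0.0131, or adjusted p = 0.104 with an estimated correlation). NOTCH targets had 0.19 (camera adjusted p = 0.0154, or adjusted p = 0.233 with an estimated correlation). S phase had 0.09 (camera adjusted p = 0.0131, or adjusted p = 0.325 with an estimated correlation). G2/M had 0.11 (camera adjusted p = 7.28e-05, or adjusted p = 0.268 with an estimated correlation). Glycolysis and hypoxia had -0.07 (camera adjusted p = 0.03, or adjusted p = 0.38 with an estimated correlation). Ribosomal proteins had -0.11 (camera adjusted p = 5.11e-07, or adjusted p = 0.426 with an estimated correlation).

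Between days, Jurkat showed a shift in stress genes. edgeR called 1 gene of 22032 for the day 10 change minus the day 8 change, HSPA5, which encodes the endoplasmic reticulum chaperone BiP, at -0.87 ± 0.10 (adjusted p = 0.0141). It changed by 0.66 at day 8 and by -0.20 at day 10. At an unadjusted p under 0.05 there were 1468 genes, DESeq2 called 57, and fits without 1 library called 0 to 7. HSPA5 was lost without replicate 1 or 2 of day 8 sh-NC, replicate 2 of day 8 sh-SH2D1A, replicate 1 of day 10 sh-NC or replicate 2 of day 10 sh-SH2D1A. As lists, heat shock and unfolded protein genes had a lower change at day 10 than at day 8, with a median of -0.28 over 26 genes (camera adjusted p = 3.53e-08, or adjusted p = 0.011 with an estimated correlation), and ATF4 targets one of -0.29 over 30 (camera adjusted p = 6.33e-07, or adjusted p = 0.0104 with an estimated correlation). SH2D1A differed between days by 0.11 ± 0.13 (edgeR adjusted p = 0.952) and CHI3L2 by 0.28 ± 0.09 (edgeR adjusted p = 0.535). The remaining lists that passed with the preset correlation are given by their median: Chitinase family at 0.19 (camera adjusted p = 0.034, or adjusted p = 0.166 with an estimated correlation). MYC targets had -0.08 (camera adjusted p = 0.00621, or adjusted p = 0.142 with an estimated correlation). S phase had -0.07 (camera adjusted p = 0.037, or adjusted p = 0.501 with an estimated correlation). Glycolysis and hypoxia had 0.11 (camera adjusted p = 0.00243, or adjusted p = 0.306 with an estimated correlation).

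In 6T-CEM the changes in SH2D1A and CHI3L2 were smaller at day 10 than at day 5, by 0.72 ± 0.13 (edgeR adjusted p = 0.0181) and 0.55 ± 0.09 (edgeR adjusted p = 0.0125). edgeR called 89 genes with a higher change at day 10 and 61 with a lower one. Cholesterol synthesis genes had a median difference of 0.34 over 29 genes (camera adjusted p = 2.76e-12, or adjusted p = 0.00084 with an estimated correlation), with SQLE, a rate-limiting sterol enzyme, at 0.53 ± 0.09 and SREBF2, the master regulator of the pathway, at 0.48 ± 0.10. ERK and immediate early targets had one of 0.34 over 29 (camera adjusted p = 0.000111, or adjusted p = 0.036 with an estimated correlation), with JUN at 1.56 ± 0.22 and SPRY2, an ERK pathway inhibitor gene, at 1.08 ± 0.16. HLA genes had one of 0.44 over 16 (camera adjusted p = 0.000111, or adjusted p = 0.137 with an estimated correlation), with HLA-B at 1.42 ± 0.17. CDHR1, a photoreceptor cadherin gene, was lower than sh-NC by 1.03 on the log2 scale at day 5 and higher by 1.39 at day 10. The difference was 2.42 ± 0.11 (edgeR adjusted p = 1.24e-07). Its level moved mainly in the control, from 58.4 CPM at day 5 to 12.6 at day 10 with sh-NC, against 28.5 and 32.9 with sh-SH2D1A. GPA33 differed by -2.01 ± 0.23 and PCDH10 by -2.10 ± 0.29. PCDH10 too moved mainly in the control, from 2.94 to 11.2 CPM with sh-NC and from 17.7 to 15.7 with sh-SH2D1A. GPA33 moved in both arms, from 3.56 to 6.91 CPM with sh-NC and from 12.7 to 6.10 with sh-SH2D1A. Without replicate 1 or 2 of day 10 sh-NC the SH2D1A and CHI3L2 differences no longer passed, and the count of 150 went to 27 and 24. The SH2D1A difference was also lost without replicate 2 of day 5 sh-NC or replicate 1 of day 10 sh-SH2D1A. The count went to 46 and 49 without either day 10 sh-SH2D1A library, to 1684 and 253 without replicate 1 or 2 of day 5 sh-SH2D1A, and to 612 with DESeq2. A total of 11 lists passed with the preset correlation, and the others are given by their median: Chitinase family at 0.21 (camera adjusted p = 0.0494, or adjusted p = 0.18 with an estimated correlation). NF-kB targets had 0.22 (camera adjusted p = 0.000208, or adjusted p = 0.137 with an estimated correlation). MYC targets had -0.18 (camera adjusted p = 0.00019, or adjusted p = 0.0514 with an estimated correlation). S phase had 0.16 (camera adjusted p = 1.67e-05, or adjusted p = 0.137 with an estimated correlation). G2/M had 0.10 (camera adjusted p = 0.000208, or adjusted p = 0.336 with an estimated correlation). Glycolysis and hypoxia had 0.21 (camera adjusted p = 0.000179, or adjusted p = 0.182 with an estimated correlation). Ribosomal proteins had -0.12 (camera adjusted p = 0.000195, or adjusted p = 0.636 with an estimated correlation). Mitochondrially encoded genes had -0.33 (camera adjusted p = 2.41e-05, or adjusted p = 0.351 with an estimated correlation).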

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

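Both tests of explanations for the day difference in 6T-CEM were chosen after the result was seen, while the test of read-through genes and the counts of other splits were set before.

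The Jurkat and 6T-CEM changes differed by a test of the difference itself in 418 genes. By the same test the difference was -0.28 for CHI3L2, 5.15 for SIX4, 3.99 for PTPRG, 3.68 for TRPS1, 3.66 for RASSF8-AS1, -3.60 for SNHG9, -3.37 for TC2N, -2.72 for SCG2, -2.40 for CBLL1-AS1 and -2.23 for RAPH1. The values of SIX4, TRPS1, PTPRG, RASSF8-AS1, SNHG9, CBLL1-AS1 and TC2N rest on groups at or near 0 and are no bounds. SIX4 was at least 6.83-fold higher in Jurkat at day 10, TRPS1 at least 8.23-fold higher in Jurkat at day 8 and SNHG9 at least 6.68-fold higher in 6T-CEM at day 5. SNHG9 was not called in that comparison (edgeR adjusted p = 0.0614), where it had 14 and 25 counts with sh-SH2D1A. Of the 16 fits without 1 library, the call of CHI3L2 was lost in 13, of SENP3-EIF4A1 in 11, of RASSF8-AS1 in 10, of PTPRG and TRPS1 in 9, and of CBLL1-AS1 in 8. Among 100 splits of the libraries within tables, 4 gave at least 418 genes, the real one included, and the highest other gave 2232. The 3 others exchange the arms of 6T-CEM tables, which turns the difference into a sum, and so follow the structure of the design. Such splits test for no shRNA effect in any table, not for an equal effect in both lines. They therefore cannot exclude chance for the line difference. For the mean of the 4 changes, 1 of 100 splits, the real one, gave at least 5063 genes and the highest other gave 2094. Chance in the labelling of libraries can be excluded for that mean at this share.

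Read-through genes stood among the largest changes, and SENP3-EIF4A1 differed between the lines by 3.81. They made up 4.27% of the calls of at least 2-fold in Jurkat at day 8, 3.07% at day 10, 0.56% in 6T-CEM at day 5 and 1.98% at day 10, against 0.36 to 0.38% of tested genes. If counts move between a read-through gene and the genes it overlaps, replicates should differ as well. Over 78 such genes the median absolute log2 ratio between replicates was 0.416, against 0.200 for genes of like level, 2.08 times as large, and 9.71% of pairs had a replicate at 0 against 0.069%. The assignment of reads may therefore account for changes of read-through genes as a set. It was not shown for BIVM-ERCC5, whose replicates agreed in Jurkat at day 8, at 78.1 and 81.1 CPM with sh-NC and 0 with sh-SH2D1A. Whether the genes it overlaps moved the other way was not tested. A change in splicing or termination was not tested either and stays open.

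Between days in Jurkat the test of the difference called 1 gene, HSPA5 at -0.87. Of 100 splits, 68 gave as many and the highest other gave 1223, so chance cannot be excluded for this count, and splits with far more genes exchange the arms of a Jurkat table.

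The changes differed between days 5 and 10 in 6T-CEM in 150 genes, among them SH2D1A at 0.72 and CHI3L2 at 0.55, and of 100 splits 9 gave as many, the highest other 2520, so chance cannot be excluded for the count by this measure. The 8 others exchange the arms of a 6T-CEM table, a structure of the samples. A weaker effect at day 10, where SH2D1A fell less, would leave smaller changes of the same sign, and 44 of 148 genes (29.7%) changed more at day 10 and 89 had opposite signs, but these genes were chosen for their difference, which favours opposite signs, so a weaker effect stays open. Replicate 2 of day 5 sh-SH2D1A, whose pair differed most, is not the sole source, since 127 of the 150 (84.7%) were called in the same direction without it, and 150 without replicate 1. Only 24 or 23 were called without replicate 1 or 2 of day 10 sh-NC, although all 150 kept their sign, and time since knockdown, growth state and culture stay open too.

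The same difference was 2.90 for SLAMF7, 2.42 for CDHR1, 2.0 for EPHA10, 1.96 for BEGAIN and 1.94 for ADAT3, whose span overlaps SCAMP4. It was -7.67 for SNHG9, a value that rests on a group at 0 and is no bound, -3.21 for SCUBE1, -2.10 for PCDH10, -2.01 for GPA33 and -1.98 for MIR223HG. Of the 16 fits without 1 library, the call was lost in 14 for EPHA10, 11 for SLAMF7 and BEGAIN, 4 for MIR223HG, 2 for PCDH10, 1 for SCUBE1 and 0 for CDHR1, GPA33, ADAT3 and SNHG9. For the single comparisons the 3 splits of 4 libraries are too few for a share under 0.05, and the real counts were 2381, 721, 412 and 2752 against 1, 2, 5 and 0 for the highest other split by edgeR.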

How the results depend on the processing

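The list test over 16 libraries was chosen after the result was seen, and the other tests given here were planned. In it 13 of 28 lists passed for the mean of the 4 changes, and 6 of these were lost with an estimated correlation. SH2D1A and CHI3L2 kept direction and call in all 4 comparisons with DESeq2 size factors, the DESeq2 test, the stricter filter, the block, all 16 libraries and each library left out. The 2-fold threshold was applied to counts alone, and in 6T-CEM at day 10 both changed by less than 2-fold. With no filter on low counts they changed by -1.60 and -1.35 in Jurkat at day 10 with an adjusted p = 0.139 from edgeR, where the test covers 34173 genes. No result changed direction. DESeq2 size factors and the stricter filter left all 17 main results within 1.5 times or on the same side of the threshold.

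Counts of changed genes moved by over 1.5 times as follows. With no filter they were 873 in Jurkat at day 8, 0 at day 10 (edgeR, 3533 at an unadjusted p under 0.05, and 1054 by DESeq2 with the filter), 1099 in 6T-CEM at day 10, 3 for the Jurkat day difference and 0 for genes called in all 4. With the DESeq2 test they were 1118 in 6T-CEM at day 5, 877 for the line difference, 57 and 612 for the day differences in Jurkat and 6T-CEM, and 264 for genes called in all 4. With all 16 libraries in the fit they were 1323 in Jurkat at day 8, 3108 and 916 in 6T-CEM at days 5 and 10, and 219 in all 4. With the replicate number as a block (replicate block), which these data give no ground to treat as paired, they were 1423 in Jurkat at day 10, 2188 in 6T-CEM at day 5, 660 for the line difference, 297 for the 6T-CEM day difference and 320 in all 4. With a change of at least 2-fold they were 211, 163, 178 and 303 in the single comparisons, 321 for the mean, 89 for the line difference, 0 and 52 for the Jurkat and 6T-CEM day differences, and 7 in all 4. The 0 for the Jurkat day difference stands beside 1468 genes at an unadjusted p under 0.05 by edgeR and 57 called by DESeq2. Leaving out 1 library gave 633 to 2978 in Jurkat at day 8, 298 to 2865 in 6T-CEM at day 5, 196 to 981 for the line difference, 0 to 7 for the Jurkat and 24 to 1684 for the 6T-CEM day difference, and 70 to 216 in all 4. The filter and the 2-fold threshold change which genes are tested or counted, and for the others the cause was not tested.

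Of 79 named calls in single comparisons, DESeq2 lost 25, no filter 33, all 16 libraries 18 and the block 1, and leaving out a library lost 34 of 316. Of 43 list calls, an estimated correlation lost 43, fry 14, the block 2 and leaving out a library 29 of 172. Depth limits genes near the floor of 3 counts, and with 2 libraries per arm the simulated data gave a recovery of 10.1% of 1.5-fold changes in 6T-CEM at day 5.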

Other observations

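The tests of the shared word without its overlapping words, of its share among the genes and of its copies in CHI3L2 were chosen after the result was seen. By camera, neither the BCL2 family of apoptosis genes nor the respiratory chain shifted as a list, while single members changed. In the BCL2 family, 5 of 15 genes fell in Jurkat at each day, 1 at day 5 in 6T-CEM and 3 fell and 3 rose at day 10 (camera adjusted p = 0.627, 0.214, 0.0972 and 0.546). By fry the family was lower in Jurkat at day 8 (adjusted p = 0.0173) and in 6T-CEM at day 10 (adjusted p = 0.0366). BCL2, the anti-apoptotic member, changed by -0.56 ± 0.06, -0.55 ± 0.09, -1.25 ± 0.17 and -1.16 ± 0.06. In the respiratory chain 5, 2, 3 and 4 of 44 genes fell and 0, 0, 0 and 2 rose (camera adjusted p = 0.146, 0.85, 0.281 and 0.763). NDUFA1, a subunit of complex I, changed by -0.92 ± 0.12, -0.92 ± 0.17, -1.28 ± 0.25 and -1.23 ± 0.12, and SDHD, a subunit of complex II, by -0.70 ± 0.09, -0.50 ± 0.10, -0.94 ± 0.13 and -0.57 ± 0.05. Among STAT5 and cytokine targets 3, 2, 1 and 3 fell and 0, 0, 1 and 4 rose (camera adjusted p = 0.445, 0.214, 0.955 and 0.918), and by fry they were lower in Jurkat at day 8 (adjusted p = 0.0366) and in 6T-CEM at day 10 (adjusted p = 0.0178), with CCND3, which encodes cyclin D3, at -0.52 ± 0.05 in Jurkat at day 8. Of NOTCH targets in Jurkat at day 8, 4 of 18 rose and 2 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0127, or adjusted p = 0.229 with an estimated correlation), with PTCRA, the pre-T cell receptor alpha chain gene, at 0.88 ± 0.10. Without sh-NC replicate 1 or 2 that list had an adjusted p = 0.0625 and 0.0529 by camera.

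ATF4 targets, ribosomal proteins and mitochondrially encoded genes also passed in Jurkat at day 8, ATF4 targets in the direction opposite to day 10 and ribosomal proteins opposite to 6T-CEM at day 5. ATF4 targets had 11 of 28 up and 2 down there, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.0273, or adjusted p = 0.612 with an estimated correlation), with the amino acid transporter gene SLC7A5 at 0.45 ± 0.05. That call was lost without sh-NC replicate 1 (adjusted p = 0.221), sh-SH2D1A replicate 1 (0.0517) or sh-SH2D1A replicate 2 (0.0631). Ribosomal proteins had 7 of 71 down and 0 up, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.06e-05, or adjusted p = 0.612 with an estimated correlation). By fry these 3 lists had an adjusted p = 0.0979, 0.221 and 0.239. Mitochondrially encoded genes had 5 of 13 up and 0 down, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0111, or adjusted p = 0.612 with an estimated correlation), a call lost without sh-NC replicate 1 (adjusted p = 0.209). Histone genes had 0, 1, 0 and 0 down and 0, 0, 1 and 1 up (camera adjusted p = 0.445, 0.74, 0.955 and 0.918). By camera, markers of other cell types did not shift as lists in the single comparisons. The camera adjusted p was 0.684, 0.295, 0.507 and 0.147 for B cells, 0.478, 0.727, 0.281 and 0.451 for myeloid cells, 0.478, 0.956, 0.561 and 0.451 for epithelial and packaging cells, and 0.219, 0.243, 0.281 and 0.782 for erythroid cells. By fry, B cell markers were lower in 6T-CEM at day 10 (adjusted p = 0.0178) and myeloid markers higher at day 5 (adjusted p = 0.042), and for Jurkat minus 6T-CEM epithelial and packaging cell markers were higher by camera (adjusted p = 0.0446, or adjusted p = 0.233 with an estimated correlation). Members past the threshold were CD79A at -0.65 ± 0.08 and CD79B at -1.09 ± 0.26 in 6T-CEM at day 10, VIM, which T cells express too, at -0.38 ± 0.05, -0.52 ± 0.10 and -0.43 ± 0.03 in Jurkat at day 8 and 6T-CEM at days 5 and 10, and TFRC, a receptor of dividing cells, at 0.34 ± 0.05, 0.58 ± 0.08 and -0.13 ± 0.03 in Jurkat at days 8 and 10 and 6T-CEM at day 10. HBA1 and HBA2 changed by 1.61 ± 0.29 and 1.31 ± 0.34 in 6T-CEM at day 10, from 0.844 and 0.658 CPM.

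The median, the mean and the direction of camera differed in sign in Jurkat day 8 for T-ALL and thymocyte identity and BCL2 family, in Jurkat day 10 for STAT5 and cytokine targets, Respiratory chain, Interferon response, Myeloid markers and Epithelial and packaging cell markers, in 6T-CEM day 5 for STAT5 and cytokine targets, NOTCH targets, T-ALL and thymocyte identity, Histones and Erythroid markers, and in 6T-CEM day 10 for STAT5 and cytokine targets, Histones and Erythroid markers. None of these lists passed there by camera. By fry, lists that camera did not pass were T-ALL and thymocyte identity and effector T cell genes in Jurkat at day 8, both lower (adjusted p = 0.0481 and 0.0366), and chitinase family and interferon response at day 10, both lower (adjusted p = 0.0398 and 0.0322). In 6T-CEM at day 10 they were ERK targets, NF-kB targets, the chitinase family and ATF4 targets, all lower at an adjusted p = 0.0178, S phase (adjusted p = 0.00183), G2/M (adjusted p = 0.0306) and p53 targets (adjusted p = 0.0286), lower too, and interferon response (adjusted p = 0.0387), higher.

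Of the genes lower in all 4 comparisons 47 of 113 carry the word GGTTACA in their 3' UTRs, and a candidate explanation is unintended binding by the shRNA, whose sequence is not given in the sources used here. Of 16270 words, GGTTACA had the lowest z over the mean of the 4 changes, rank 1, at -15.394, and it lies in SH2D1A, but 12.92% of all words do. Its z was -11.4 and -10.2 in Jurkat at days 8 and 10, and -14.2 and -13.5 in 6T-CEM at days 5 and 10. In 20 runs with the mean changes shuffled over genes, the lowest z of any word was -4.58. Shuffling treats genes as independent, and a low z does not tell an shRNA from an endogenous regulator with the same seed. For the test of seed matches, set before the result was seen, the lowest word absent from SH2D1A had been required to be 1.5 times weaker. TGGTTAC, the same word shifted by a base, was 1.15 times weaker. Since these words overlap and can mark the same sites, that test cannot decide and leaves seed matches of the shRNA open. Without words sharing 5 bases in a row the ratio was 2.72, while the share of carriers, 3.91 times that at like 3' UTR length, is no separate support, since the word was chosen from these same changes. Long stretches shared with SH2D1A were no more frequent (3 genes against 3.64, ratio 0.824). CHI3L2 has 0 copies of GGTTACA, which covers this word alone. Since the shRNA sequence is not given, other seed matches in CHI3L2 were not tested and stay open for its fall. TBCA, NFKB1, SLAMF6, BCL2, NDUFA1 and SDHD carry the word, and an endogenous regulator with the same seed, or an indirect effect through such genes, stays open too.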
